A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

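Gene expression was measured on 8 arrays of Saccharomyces cerevisiae, 2 each for control cells and cells with a changed TFIIB, grown without or with 4 mM H2O2 and collected at an OD600 of 1.0. Per the labels' protocols, total RNA was treated with DNase, labelled with Cy3 in 1 colour and hybridised to Agilent arrays. The series' design text calls the 2 samples of a group biological replicates, and groups and replicate numbers were taken from the sample titles. All arrays lie on 1 slide and were read in 1 scan, so no slide or scan effect can be separated, and on the slide the row goes with H2O2 and the columns with the strain.

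Each scanner file holds spot intensity values that Feature Extraction 10.7.1.1 made for the authors, per the file headers, with a processed signal that is background-subtracted and a flag for spots well above background. The authors' deposited comparison tables, 1 per medium, hold a p-value and a Benjamini-Hochberg corrected p-value from an unpaired test with asymptotic p, per the file headers. They also hold an absolute fold change with its direction, per the file headers, and normalized log2 values per array that the authors made in an experiment named as quantile. The headers name a filter on a raw signal of at least 20, and how it acted was not analysed here. The tables also hold raw values per array, 8 columns in all, which were not used here. Of each table, 4 rows were emptied for this work and were not used here. The array's gene names come from the scanner files, whose grid names build sacCer2, while gene positions come from the descriptions in the authors' deposited tables, which name release R64-1-1. Of 6225 genes, 5720 matched a RefSeq gene table that was used for names alone.

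For each array the 2 spots of a probe were averaged as log2 of the processed signal, and the array's 75th percentile was subtracted. Control spots and outlier-marked spots were left out (536 control spots per array), and no spot was saturated. A gene with several probes (29 genes) was represented by the probe with the highest mean signal. The 6045 genes with a probe well above background on both arrays of at least 1 group were tested with limma 3.58.1 in R 4.3.3, in 1 fit of the 4 groups (lmFit and eBayes, 4 residual degrees of freedom, 3.10 prior degrees of freedom). All p-values of genes are two-sided, adjusted by Benjamini-Hochberg within each of 5 comparisons and called under 0.05. They rest on the spread between arrays of the same group, pooled over the 4 groups for each gene. The SD of replicate differences ran from 0.14 (control cells without H2O2) to 0.62 (arrays labelled mutant without H2O2). The pooled spread may therefore differ from that of the groups compared. Where a probe was not well above background on either array of 1 group, the fold is a bound. It sets the bright group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array, as means of scaled log2 values, and no fold is given where it is under 1 or both groups are below background. Medians of lists are of fitted values, without regard to bounds. A range of a list's median over scalings covers the 75th percentile, the median of each array, quantile normalization, normexp with either, the E1A spike-in probes and the percentile over well-measured genes. Of 44 gene lists covering 1265 genes on the array, each was tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, adjusted over the 44 lists.

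The groups, the tests, the 44 lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took SUA7, then the 10 largest rises and 10 largest falls past the threshold with replicates not overlapping among genes with a standard name (5 each way for H2O2 on the arrays labelled mutant and for the interaction, filled up by the smallest p where fewer passed). For each list described it took up to 4 members with the smallest p, and up to 2 members past the threshold that went against the list. The alternatives were other scalings (median, quantile), normexp background correction with an offset of 50, other filters on dim probes, all probes of a gene averaged, fits of the compared groups alone, the replicate number as a block, a variance trend, other thresholds, the authors' normalized values and leaving out each array in turn. The planned normexp step named a mean signal column, and the median signal and median background of each spot were used instead. Chosen after seeing the data were scaling on 7 of 10 E1A spike-in probes, a percentile over genes well above background on all 8 arrays, a minimum of 100 units on all 8 arrays, averaging the control arrays without H2O2, and the unpaired test named in the table headers.

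The fit was tested on simulated data for H2O2 in control cells, with 200 of 6045 genes changed. With a log2 change of 1 it recovered 36.5% of them at the spread of all arrays (5 false calls). A fit of the 4 control arrays alone, at their own spread, recovered 66% (8 false calls). With a log2 change of 2 the fit of all arrays recovered 86% (8 false calls) and that of the control arrays alone 91.5% (9 false calls). The latter is not the fit behind the main counts. The simulation drew genes independently and gave all arrays of a gene the same spread. In the data the SD of replicate differences was 0.14 for control cells without H2O2 and 0.44 with H2O2. The counts of false calls may therefore not carry over to the data. Signal over background, not a read count, sets the depth of these arrays, and it was far lower on the arrays labelled mutant. No genome sequence was used here, and the position of a probe within its gene was not analysed here.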

Results

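The series measured transcript levels in Saccharomyces cerevisiae of the CENPK.2-1C background, a laboratory strain of budding yeast, with 1-colour Agilent arrays. Control cells were set against cells carrying a mutant form of TFIIB, the general factor that helps RNA polymerase II find the transcription start. Both were sampled in exponential phase at an OD600 of 1.0, from rich glucose medium without or with 4 mM hydrogen peroxide (H2O2), which oxidises thiols, iron centres and other cell components. The 8 arrays form 4 groups of 2, which the series describes as biological replicates, and all 8 lie on 1 slide read in 1 scan. The design asks how the mutant differs from the control in each medium, and by extension what H2O2 does in each strain and whether that response differs. The number of arrays, 2 per group, limits the precision of every value below; ± after a log2 change is its standard error in the fit, and ± after a signal is the SD of 2 arrays.

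TFIIB is encoded by SUA7 (YPR086W), placed by the authors' deposited tables on chromosome XVI at 710101 to 711138 on the plus strand of release R64-1-1. Its probe read 27713 ± 4377 units on the control arrays without H2O2 and 20759 ± 9858 units on those with H2O2. On the arrays labelled mutant it read 6.22 ± 0.187 and 8.05 ± 2.36 units, and was not well above background on any of the 4. A probe does not see a base change, so this level does not show which form of TFIIB the cells carried. The same loss covered most of the array. The median probe read 3547 to 6022 units on the 4 control arrays and 6.04 to 9.75 units on the 4 arrays labelled mutant, while the E1A spike-in probes, which report labelled RNA added during preparation, read 2622 to 4078 and 3210 to 4696 units. Between 94.7% and 97.2% of probes were well above background on the control arrays, against 21.8% to 41.2% on the arrays labelled mutant. Log2 signals of the control arrays correlated across genes at r = 0.939 to 0.998, and those of the arrays labelled mutant at 0.924 to 0.963. Control with mutant arrays correlated at 0.190 to 0.239 (genes are not independent replicates).

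**Figure D1:**
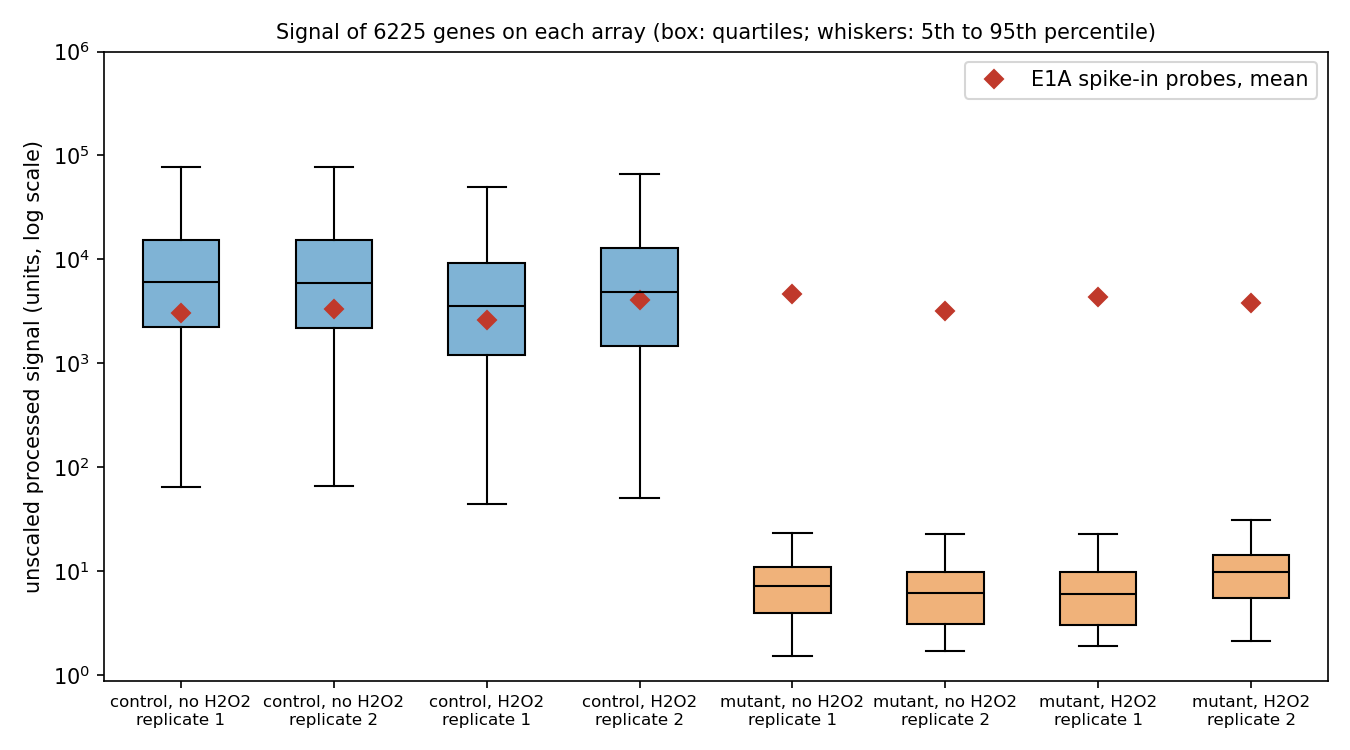
Unscaled processed signal (units, log scale) of 6225 genes on each of the 8 arrays, with boxes for the quartiles, a line for the median, whiskers for the 5th to 95th percentile, and diamonds for the mean of the E1A spike-in probes. Medians lie at 3547 to 6022 units on the control arrays and at 6.04 to 9.75 units on the arrays labelled mutant, whereas the spike-in probes read 2622 to 4696 units on all of them.

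A small set of genes stayed bright on the arrays labelled mutant. There, 122 of 6225 genes (1.96%) read at least 100 units on all 4 arrays, and 5512 genes (88.5%) read under 20 units on all 4. The bright set held 33 of the 136 ribosomal protein genes (24.3%), among them RPL40A with 64196 units without and 73062 units with H2O2. It also held the glycolytic genes GPM1 (phosphoglycerate mutase) with 54492 units and ENO1 (enolase) with 26893 units without H2O2, and GLN1 (glutamine synthetase) with 126853 units. In contrast FBA1 (fructose-bisphosphate aldolase), at 580840 units on the control arrays without H2O2, read 2.28 units on the matching arrays labelled mutant. RPL5 read 348141 and 2.09 units and ADH1 (alcohol dehydrogenase) 533496 and 4.26 units in the same comparison.

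**Figure D2:**
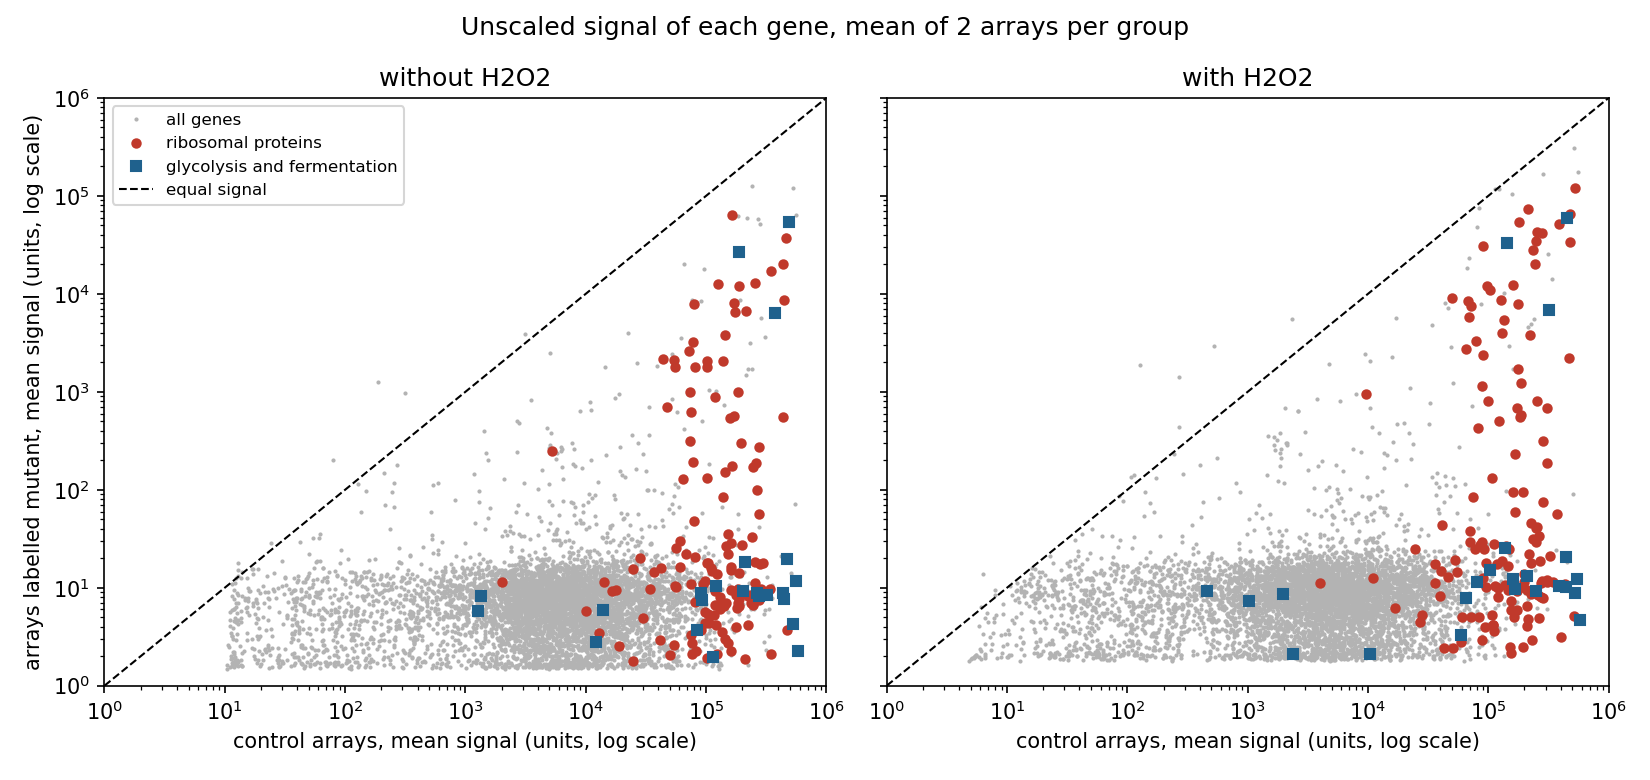
Unscaled signal of each gene (units, log scales), mean of the control arrays on the x axis and of the arrays labelled mutant on the y axis, without H2O2 (left) and with H2O2 (right), 2 arrays per mean. Most genes (88.5%) read under 20 units on all 4 arrays labelled mutant whatever their control level, while 33 of the 136 ribosomal protein genes (red) and 3 of the 23 glycolysis and fermentation genes (blue squares) read at least 100 units on all 4.

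In control cells with H2O2, the genes that rose included many of ribosome assembly, and those that fell many of reserve carbohydrates, gluconeogenesis, alternative hexose transporters, thiamine synthesis and the general stress response. Of these groups tested as lists, only thiamine synthesis held with an estimated correlation. Of 6045 genes tested, 790 rose and 847 fell at an adjusted p under 0.05 (limma, 75th percentile scale). The 10 largest rises among genes with a standard name included RRN11 and RPA12, of the RNA polymerase I machinery that transcribes ribosomal RNA, at 2.73 ± 0.36 (adjusted p = 0.00480) and 2.18 ± 0.34 (adjusted p = 0.00620). BFR2 and UTP18, of the small-subunit processome, rose by 2.51 and 2.13, and REI1 and SSF1, which act in maturation of the large subunit, by 2.06 and 2.05. The others were BSC1 (2.66), the plasma membrane exporter AQR1 (2.46), and VTS1 (2.36) and NRP1 (2.23), of which VTS1 encodes an RNA-binding protein. RRN11 read 637 ± 62.8 units without and 3470.0 ± 2510.4 units with H2O2.

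The 10 largest falls were led by RGI2, a gene of respiratory growth, at -5.03 ± 0.79 (adjusted p = 0.00679), or 32.6-fold, from 7415 ± 751 to 219.8 ± 213 units. GPH1 (glycogen phosphorylase) fell 30.7-fold, GLC3 (glycogen branching enzyme) 18.8-fold, TSL1 (a trehalose synthase subunit) 17.0-fold and GAC1, which targets a phosphatase to glycogen synthase, 16.9-fold. MAN2 and DSF1, near-identical mannitol dehydrogenase genes whose probes may not separate them, fell 27.2-fold and 23.9-fold. HXT15, of the hexose transporter family, fell by 4.39 on the log2 scale, EGO4 fell 20.3-fold and RTN2 18.8-fold. Adjusted p of these 10 ranged from 0.00313 (HXT15) to 0.0361 (GAC1). SUA7 itself showed no detectable change with H2O2 (0.0079 ± 0.22, adjusted p = 0.983).

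By gene group, 61 of 86 ribosome biogenesis genes rose and none fell, 76 when adjusted over the list alone, with a median of 1.00, or 0.46 on the spike-in scale (camera adjusted p = 1.19e-22; adjusted p = 0.0627 with an estimated correlation). Examples besides BFR2 and UTP18 are UTP14 at 1.71 ± 0.16 and MAK16 at 1.75 ± 0.18. Of 136 ribosomal protein genes, 50 rose and none fell, 57 adjusted over the list alone, with a median of 0.74, or 0.20 on the spike-in scale (camera adjusted p = 1.75e-12; adjusted p = 0.261 with an estimated correlation). RPS27A rose by 1.44, RPL7B by 1.42, RPP2B by 1.28 and RPS30B by 0.99. Most ribosomal protein genes have a close copy, so a rise of one copy is uncertain as to which. In the general transcription factor list, 5 of 36 genes rose, 3 adjusted over the list alone, with a median of 0.29 that turns to -0.25 on the spike-in scale (camera adjusted p = 0.0205; adjusted p = 0.261 with an estimated correlation). MOT1, which removes TATA-binding protein from DNA, rose by 1.68, and the TFIID subunits TAF1, TAF5 and TAF3 by 0.92, 0.66 and 0.61.

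Among the lists that camera called down, 19 of 22 gluconeogenesis and glyoxylate cycle genes fell, 20 adjusted over the list alone (median -2.57, -3.11 to -1.31 over scalings; camera adjusted p = 8.34e-11; adjusted p = 0.261 with an estimated correlation). ICL1 (isocitrate lyase) fell 10.6-fold, FBP1 (fructose-1,6-bisphosphatase) 5.01-fold, IDP2 4.48-fold and ACS1 (acetyl-CoA synthetase) 4.24-fold. In reserve carbohydrate metabolism, 16 of 20 trehalose and glycogen genes fell, 17 adjusted over the list alone (median -2.10, -2.64 to -1.28 over scalings; camera adjusted p = 6e-09; adjusted p = 0.261 with an estimated correlation). GDB1 (glycogen debranching enzyme) fell 5.14-fold, UGP1 (UDP-glucose pyrophosphorylase) 3.18-fold and ATH1 (acid trehalase) 3.17-fold, beside TSL1. For sugar uptake, 15 of 20 hexose transport genes fell, 15 adjusted over the list alone (median -1.66, -2.20 to -0.61 over scalings; camera adjusted p = 2.86e-07; adjusted p = 0.261 with an estimated correlation). HXT17 and HXT16 fell 16.0-fold and 15.4-fold, but with HXT15 they are near-identical and are uncertain as to copy, and HXT10 fell 3.62-fold. STD1, a regulator of glucose-responsive genes, rose by 0.59 against the direction of that list.

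Genes of stress and respiration were also among the falls. Of the genes that rise in many stresses (the environmental stress response), 37 of 44 list members fell, 42 adjusted over the list alone (median -2.34, -2.88 to -1.27 over scalings; camera adjusted p = 7.61e-16; adjusted p = 0.309 with an estimated correlation). HSP12, a small membrane-associated stress protein, fell 11.5-fold, YGP1 8.44-fold and TKL2 (transketolase) 4.90-fold, while SSA3, an HSP70 chaperone, rose by 0.87. Of genes for peroxide and thiol defence, 12 of 35 list members fell, 12 adjusted over the list alone (median -0.28, -0.83 to -0.25 over scalings; camera adjusted p = 0.00380; adjusted p = 0.261 with an estimated correlation). CTT1 (cytosolic catalase) fell 10.5-fold, TSA2 and PRX1 (peroxiredoxins) 3.94-fold and 3.34-fold, and TRR2 (mitochondrial thioredoxin reductase) 1.76-fold. Of known targets of Yap1, the main peroxide-sensing transcription factor, 5 of 22 list members fell, 7 adjusted over the list alone (median -0.32, -0.86 to -0.18 over scalings; camera adjusted p = 0.0124; adjusted p = 0.261 with an estimated correlation). ECM4 fell 5.25-fold and OYE3 2.89-fold, and the exporter gene ATR1 rose by 0.87. For thiamine synthesis, 14 of 20 list members fell, 17 adjusted over the list alone (median -1.49, -2.03 to -0.59 over scalings; camera adjusted p = 4.3e-10; adjusted p = 0.0470 with an estimated correlation). THI2, PET18, THI7 and SNZ2 (uncertain as to copy) fell 8.14-, 10.1-, 6.15- and 5.12-fold. In the respiratory chain, 20 of 40 list members fell, 21 adjusted over the list alone (median -0.65, -1.20 to -0.43 over scalings; camera adjusted p = 1.44e-08; adjusted p = 0.0470 with an estimated correlation). NDE2 fell 7.64-fold, and the succinate dehydrogenase genes SDH1, SDH2 and SDH4 fell 3.41-, 2.90- and 2.44-fold.

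**Figure D3:**
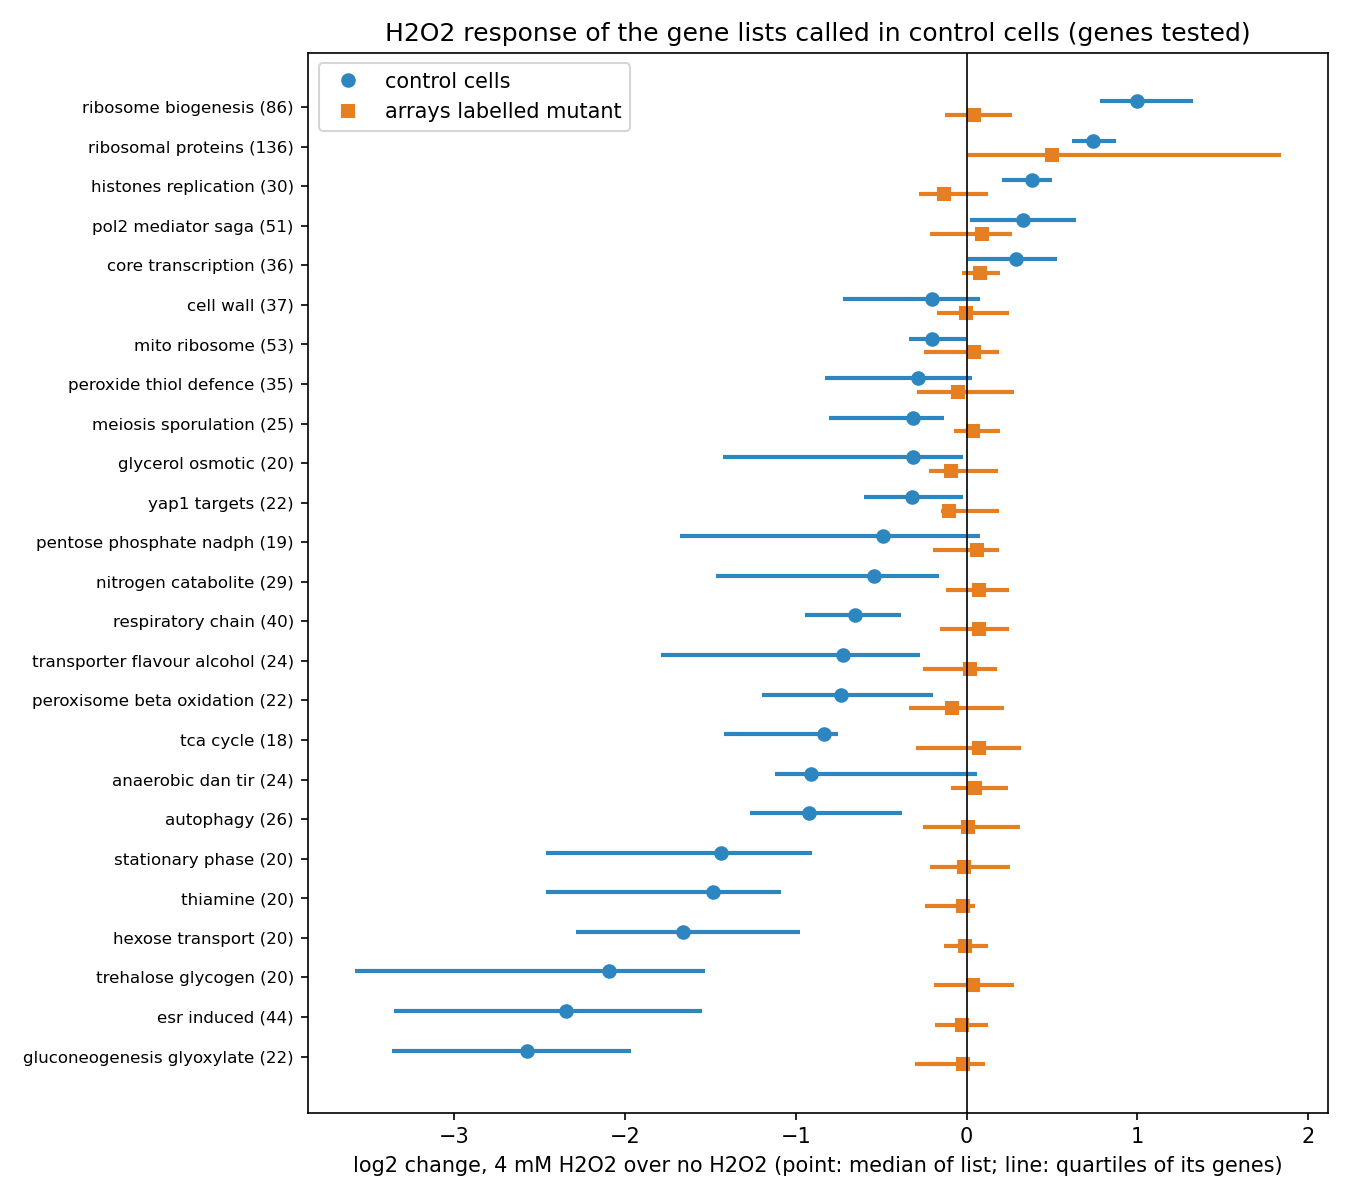
Log2 change with 4 mM H2O2 of the 25 gene lists called in control cells (camera), as the median (point) and quartiles (line) of each list's genes, in control cells (blue circles) and on the arrays labelled mutant (orange squares), on the 75th percentile scale; the number of genes tested is in brackets. Medians in control cells run from -2.57 (gluconeogenesis and glyoxylate cycle) to 1.00 (ribosome biogenesis), and those of histones and replication, of RNA polymerase II with Mediator and SAGA, and of general transcription factors, all above 0 here, lie below 0 on the spike-in scale.

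In all, 25 of 44 lists were called for H2O2 in control cells (5 up and 20 down), of which the thiamine and respiratory chain lists also held with an estimated correlation. The count of genes rests on the control arrays without H2O2, which differed from each other far less than other pairs. It is thus in doubt whether they are separate cultures. The p-values of every comparison with that group take them to be. Their SD on the log2 scale was 0.0965, a variance of 1.53 times that of duplicate spots, against 65.8 times for the control arrays with H2O2. Averaged and counted as 1 sample, an alternative chosen after seeing the data, they left 124 genes (38 rises and 86 falls), all 124 among the calls above. Another scaling also moved the split, to 29 rises and 957 falls on the E1A spike-in probes (median of all genes -0.51, against 0.032), 36 rises and 74 falls after quantile normalization and 14 rises and 45 falls after normexp with quantile normalization. The count grew to 2270 rises and 1965 falls after normexp with the 75th percentile, and to 1906 rises and 1567 falls with the compared arrays fitted alone.

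Without H2O2, the arrays labelled mutant differed from the control arrays at 4791 of 6045 genes, with 3050 higher and 1741 lower relative to each array's 75th percentile (limma, adjusted p under 0.05). That percentile lay at 9.87 and 10.96 units on these arrays labelled mutant and at 15403 and 15424 units on the control arrays, so a gene at background on both counts as higher. Scaled on the E1A spike-in probes, 3 genes were higher and 6021 lower, and 3026 of the 3050 became falls. The median of all genes moved from 0.63 to -10.19. Of the 4791 genes, 4171 (87.1%) read under 20 units on all 4 arrays labelled mutant.

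The 10 largest falls without H2O2, ranked by the fitted change and not by the bound, were highly expressed genes of the control cells. They kept a negative log2 change past the threshold under all 23 alternative settings that tested them. Filters asking for signal on all arrays left them out. As their probes were near background on the arrays labelled mutant, this agreement was favoured in advance. FBA1 was at least 51.8-fold lower (adjusted p = 1.09e-07). RPL5 (at least 31.1-fold), RPS31 (at least 42.2-fold) and RPL9A (at least 19.0-fold) encode ribosomal proteins. ADH1 was at least 47.6-fold lower, and OLE1 (fatty acid desaturase) at least 29.7-fold. The cell wall genes SED1, CIS3 and CWP1 were at least 28.1-, 19.8- and 11.4-fold lower, and LEU4, of leucine synthesis, at least 11.9-fold. All are bounds because no probe of these 10 was well above background on an array labelled mutant without H2O2. SUA7 was at least 2.46-fold lower (adjusted p = 0.000373), and at least 4443-fold on the spike-in scale.

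The 10 largest rises on the 75th percentile scale, ranked by the fitted change, include 9 with only a bound, as no probe of these was well above background on a control array without H2O2: RDS1 (at least 731-fold, adjusted p = 3.16e-07), ENA5 (at least 384-fold), BI4 (at least 338-fold), BI3 (at least 286-fold), GMC2 (at least 392.2-fold), ECM12 (at least 214-fold), ARN2 (at least 249.5-fold), AYT1 (at least 472-fold) and COS8 (at least 231-fold), and all but RDS1 had a fitted change below 0 on the spike-in scale. The remaining 1, MF(ALPHA)1, had a log2 change of 9.72, and -1.10 on the spike-in scale. These genes were near the floor on both kinds of array. RDS1 read 24.4 units on the control and 28.9 units on the mutant arrays, and MF(ALPHA)1, an alpha-factor gene, 61.6 and 35.4 units. MF(ALPHA)1 was well above background on 1 of the control arrays without H2O2. On the spike-in scale, the 3 genes that were higher are YLR076C (2.45), YHR140W (1.17) and YOR050C (0.88), named after their values were seen.

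Among ribosomal protein genes without H2O2, 31 were higher and 83 lower of 136, or 32 and 83 adjusted over the list alone, with a median of -2.19 and, on the spike-in scale, -13.01 (camera adjusted p = 2.88e-09; adjusted p = 0.312 with an estimated correlation). RPS1A was at least 10.8-fold lower, and RPL3 and RPS17B, each well above background on 1 mutant array, had log2 changes of -4.25 and -4.18. RPL40A, RPL7B and RPS0B had 9.17, 3.06 and 2.28, which became -1.65, -7.76 and -8.54 on the spike-in scale, and RPS0B was at -0.31 after normexp. Of 23 glycolysis and fermentation genes, 5 were higher and 17 lower, the same when adjusted over the list alone (median -4.00, spike-in scale -14.82; camera adjusted p = 7.1e-05; adjusted p = 0.174 with an estimated correlation). PGI1 (phosphoglucose isomerase), well above background on 1 mutant array as was ADH4, had -4.69, beside FBA1 and ADH1 above. GPM1 (7.33), ENO1 (7.55) and ADH4 (3.19) were higher on the 75th percentile scale and lower on the spike-in scale (-3.49, -3.27 and -7.63). Of 44 lists 2 were called up and 19 down by camera, of which none held with an estimated correlation (10 at an unadjusted p under 0.05), and fry called 40.

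Other scalings gave splits of 2332 rises and 2450 falls (median of each array), 2122 rises and 2010 falls (quantile), 4244 rises and 1320 falls (normexp, 75th percentile), 1987 rises and 1897 falls (normexp, quantile) and 2329 rises and 2338 falls (75th percentile over genes well above background on all 8 arrays, added after seeing the data), and the authors' deposited normalized values gave 1922 rises and 1896 falls. Except with the authors' values, the medians of all genes were then -0.095, -0.031, 1.27, -0.018 and -0.043.

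With H2O2 the picture was close to that without. Of 6045 genes, 3127 were higher and 1709 lower on the arrays labelled mutant (limma, adjusted p under 0.05), and on the spike-in scale 4 were higher and 6010 lower, 3092 rises having become falls. The 10 largest falls by the fitted change, all given as bounds, were RPL5 (at least 48.1-fold, adjusted p = 3.29e-07), FBA1 (at least 69.0-fold), RPS31 (at least 61.6-fold), RPL9A (at least 27.4-fold), RPL1B (at least 22.9-fold), RPP2A (at least 18.2-fold), CYS3, of cysteine synthesis (at least 16.1-fold), RPL27A (at least 17.8-fold), ADH1 (at least 60.9-fold) and RPL30 (at least 31.4-fold). SUA7 was at least 2.35-fold lower (adjusted p = 0.000581), and at least 2669-fold on the spike-in scale.

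The 10 largest rises with H2O2 were CRC1, the mitochondrial carnitine carrier, at a log2 change of 12.38 ± 0.47 (adjusted p = 4.35e-07), RCK1 (10.59), GLN1 (9.87), PET9 (9.78), ATP2 (9.70), BI4 (at least 532-fold), RDS1 (9.57, well above background on 1 control array), MF(ALPHA)1 (9.56), COS8 (at least 453-fold) and BI3, not well above background on any of the 4 arrays and so given no fold, and all but CRC1 (2.23) and RCK1 (0.44) changed sign on the spike-in scale. CRC1 read 528 units on the control and 2905 units on the mutant arrays with H2O2. In contrast PET9 (ADP/ATP carrier) read 123587 and 119124 units and ATP2 (ATP synthase subunit) 83504 and 75261 units. Both are nuclear genes that encode mitochondrial proteins. On the spike-in scale CRC1, YHR140W (3.55), YLR076C (2.10) and Q0017 (0.90) were the 4 genes that were higher, the last 3 named after their values were seen.

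Of 136 ribosomal protein genes 39 were higher and 85 lower with H2O2, the same adjusted over the list alone (median -2.43, spike-in scale -12.58; camera adjusted p = 1.4e-09; adjusted p = 0.367 with an estimated correlation). RPL3 and RPS17B were at least 25.1- and 30.7-fold lower, whereas RPL40A, RPL29 and RPS23B had 8.30, 6.22 and 6.93, turned to -1.85, -3.92 and -3.22 on the spike-in scale. Of 23 glycolysis and fermentation genes 6 were higher and 16 lower, the same adjusted over the list alone (median -3.22, spike-in scale -13.36; camera adjusted p = 0.000374; adjusted p = 0.180 with an estimated correlation). PGI1 was at least 27.1-fold lower, and GPM1, ENO1 and PDC6 (well above background on 1 mutant array) had 6.93, 7.72 and 4.20, against -3.21, -2.43 and -5.95 on the spike-in scale. ADH4 was called higher with a probe not well above background on these mutant arrays, so no fold is given, and was at least 140.0-fold lower on the spike-in scale. Camera called 4 lists up and 14 down of 44, of which none held with an estimated correlation (11 at an unadjusted p under 0.05), and fry called 41.

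For this comparison the other scalings gave 2395 rises and 2464 falls (median of each array), 2120 rises and 2016 falls (quantile), 4297 rises and 1355 falls (normexp, 75th percentile), 1988 rises and 1877 falls (normexp, quantile) and 2449 rises and 2275 falls (75th percentile over genes well above background on all 8 arrays), and the authors' deposited normalized values 2022 rises and 2061 falls. The medians of all genes were 0.73 on the 75th percentile scale, -9.42 on the spike-in scale, and -0.024, -0.014, 1.30, -0.016 and 0.093 on these. Across genes, the difference between strains with H2O2 correlated with that without at r = 0.946 (Spearman 0.931). In both media 2769 genes were called higher, against 1578 for independent lists, and 1452 lower, against 492. The correlation and the overlaps were favoured in advance, as 88.5% of genes read under 20 units on every array labelled mutant. At such genes the difference between strains mostly follows the control signal, and control arrays correlated with each other at r = 0.939 to 0.998. The overlaps therefore cannot show by themselves that an effect of the changed TFIIB recurred in both media.

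The authors' deposited table for the comparison without H2O2 lists 5946 probes, of which 1521 were up and 1228 down at a corrected p under 0.05, and the table with H2O2 lists 6025, of which 1509 were up and 1259 down. Of these calls in the authors' deposited tables, 2731 and 2755 were also tested here, 2442 and 2472 were called in the same direction, and 44 and 52 in the opposite one. In the authors' deposited table FBA1 was 10945-fold lower without and 3580.0-fold lower with H2O2, and SUA7 3.42-fold and 2.94-fold lower, values from an experiment named as quantile per the file headers, which are not bounds.

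On the arrays labelled mutant, H2O2 moved few genes past the threshold, and not under all settings. NOP58, which encodes a core protein of box C/D small nucleolar ribonucleoproteins, rose at least 2.33-fold (adjusted p = 0.0241), and YCR022C, named after its value was seen, at least 2.56-fold (adjusted p = 0.0241). NOP58 read 4.67 units without and 20.6 units with H2O2, where the control arrays read 50563 and 46137 units. The limma fit called 2 of 6045 genes, with 759 at an unadjusted p under 0.05. It called 0 after normexp with the 75th percentile (153 at an unadjusted p under 0.05), with the replicate number as a block (724), with the compared arrays fitted alone (352), with the control arrays without H2O2 averaged (475), and without any 1 of the 4 control arrays or of the 2 arrays labelled mutant with H2O2 (475 to 899). The NOP58 call ended under each of these, and on the spike-in scale, where 1 gene was called. The unpaired test named in the table headers called 1, which was neither of these 2 genes. The next smallest p-values, not past the threshold, belonged to TIF2, which has a near-identical copy (at least 2.14-fold, adjusted p = 0.0575), FUM1 (at least 1.20-fold), RPL14A (log2 change 1.11) and NSA2 with positive values, and to RPL27A (adjusted p = 0.0575), STE4 (at least 1.05-fold), GDA1, PET20 and ASH1 with negative ones. No fold is given for NSA2, RPL27A, GDA1, PET20, ASH1 and SUA7 (adjusted p = 0.879 for SUA7), as their probes were not well above background on any of the 4 arrays labelled mutant. None of the 136 ribosomal protein genes passed over all genes tested, and 2 up and 1 down did adjusted over the list alone (median 0.50, 0.064 to 0.63 over scalings; camera adjusted p = 4.15e-11; adjusted p = 0.975 with an estimated correlation). RPL34B and RPL16A, among the members with the smallest p, had a bound of at least 1.20-fold and a log2 change of 0.98. It was the 1 list of 44 that camera called; fry called 0, with 2 at an unadjusted p under 0.05. The replicates without H2O2 differed widely at the bright genes, with a variance of 136 times that of duplicate spots over 123 probes, and without replicate 1 or replicate 2 of that group 184 and 328 genes passed. Scaling on the median of each array gave 2 rises and 1 fall, quantile normalization 49 rises and 42 falls, normexp with quantile normalization 71 rises and 76 falls, and on the spike-in scale the median of all genes was 0.15, against 0.022.

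The test of whether the H2O2 response differed between the strains called 700 of 6045 genes, 363 with a more positive and 337 with a more negative change on the arrays labelled mutant (limma, adjusted p under 0.05). The largest positive differences, ranked by the fit, were at RGI2 (adjusted p = 0.0295), MAN2, GPH1, DSF1 (4.59) and RTN2 (4.46), genes that fell with H2O2 in control cells. The largest negative ones were at VTS1 (adjusted p = 0.0282), AQR1, RRN11 (-2.80, well above background on 1 mutant array in each medium), RPA12 and RNR1, of which RNR1 encodes the large subunit of ribonucleotide reductase. No size is given for RGI2, MAN2, GPH1, VTS1, AQR1, RPA12, RNR1 and SUA7 (adjusted p = 0.816 for SUA7), whose probes were not well above background on any array labelled mutant. At the 7 of these that were called, the fitted difference is mostly the change in control cells with its sign turned. Of the 700, 626 were also called for H2O2 in control cells and 694 had the opposite sign to the change there, with r = -0.883 between the 2 values across all genes tested. The design favours this, as the control arrays enter both with opposite sign. Of the 700, 620 (88.6%) read under 20 units on all 4 arrays labelled mutant, as did 88.2% of all genes tested. With the control arrays without H2O2 averaged and counted as 1 sample, limma called 0 genes (1141 at an unadjusted p under 0.05). The spike-in scale gave 459 rises and 4 falls (median of all genes 0.69, against 0.016), quantile normalization 7 rises and 4 falls, normexp with quantile normalization 33 rises and 23 falls, and normexp with the 75th percentile 1490 rises and 1892 falls.

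By group, ribosome biogenesis genes were lower in the difference at 32 of 86 members and higher at 1, 48 and 1 adjusted over the list alone (median -0.94, -0.998 to -0.27 over scalings; camera adjusted p = 2.28e-17; adjusted p = 0.101 with an estimated correlation). Genes of the environmental stress response were higher at 18 of 44, 32 adjusted over the list alone (median 2.36, 1.22 to 3.04 over scalings; camera adjusted p = 5.44e-13; adjusted p = 0.361 with an estimated correlation). Camera called 14 lists up and 2 down of 44, of which none held with an estimated correlation (5 at an unadjusted p under 0.05), and fry called 23. Across all genes the H2O2 response on the arrays labelled mutant correlated with that in control cells at r = 0.0692 (Spearman 0.0458, slope 0.0356). Over the 121 genes with at least 100 units on all 8 arrays r was 0.478 (Spearman 0.541, slope 0.607). These values rest in part on the arrays labelled mutant without H2O2, which differed widely from each other at bright genes.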

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

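Both tests of the explanations weighed here were chosen after the result was seen, whereas the test of the interaction itself was planned.

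The interaction asked whether the change with H2O2 differed between control cells and the arrays labelled mutant, and it called 700 genes and, by camera, 16 gene lists, of which none held with an estimated correlation (5 at an unadjusted p under 0.05; fry called 23). Values below are log2 differences, positive where the change was more positive on the arrays labelled mutant, and fitted also where a probe was not well above background there, in which case they measure no size. That holds at least for RGI2, MAN2, GPH1, VTS1, AQR1, RPA12, RNR1, RPL27A and GDA1, not well above background on any array labelled mutant. In reserve carbohydrate and respiratory metabolism they were RGI2 5.56, GPH1 5.05, TSL1 4.04, GDB1 1.98, UGP1 1.53 and ATH1 2.03. For hexose transporters, some near-identical, they were HXT15 4.39, HXT17 3.89, HXT16 3.74 and HXT10 1.87, and for the near-identical mannitol dehydrogenase genes MAN2 5.35 and DSF1 4.59. Glyoxylate cycle, gluconeogenesis and acetate genes gave ICL1 3.51, FBP1 1.94, ACS1 2.41, IDP2 2.10 and CRC1 2.87. Respiratory and citric acid cycle genes gave NDE2 2.82, SDH1 2.16, SDH2 1.76 and FUM1 1.54. Thiamine genes gave PET18 3.11, THI2 2.80, SNZ2 2.48 and THI7 2.22. Stress and redox genes gave CTT1 3.39, HSP12 3.36, YGP1 3.07, ECM4 2.76, PRX1 2.26, TKL2 2.23 and OYE3 1.67. Other positive values were RTN2 4.46, CWP1 1.58, SED1 1.38, PDC6 1.44 and NOP58 1.57.

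Negative differences were found for ribosome assembly and RNA polymerase I genes, with RRN11 -2.80, RPA12 -2.49, SSF1 -2.37, BFR2 -2.36, REI1 -2.30, UTP18 -2.16, MAK16 -1.85 and UTP14 -1.60. Ribosomal protein genes gave RPL27A -2.33, RPL7B -1.69, RPP2B -1.52, RPS27A -1.39, RPS30B -1.04, RPS17B -0.93 and RPL3 -0.90. The remaining values were VTS1 -3.01, AQR1 -2.82, RNR1 -2.42, NRP1 -2.30, STE4 -1.75, ECM12 -1.63, GMC2 -1.45, GDA1 -1.44, ENA5 -1.34, MOT1 -1.27 and STD1 -0.96. Counted with the control arrays without H2O2 as 1 sample, limma called 0 genes in the interaction, with 1141 at an unadjusted p under 0.05.

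The arrays labelled mutant held little signal at most of the 700 genes, as 620 of them (88.6%) read under 20 units on all 4 of those arrays. A response there could hardly be measured at these genes, so their calls alone cannot show that the response differed between strains. So did 88.2% of all genes tested read under 20 units, so the share does not set the 700 apart. At least 100 units on all 8 arrays were read at 5 of the 700, and at 121 of all 6045 genes tested. Whether the dimness accounts for the calls stays open. A loss of the H2O2 response through the changed TFIIB stays open too. Of genes with at least 100 units on all 8 arrays, 21 were called in control cells. Their median ratio of the response on the arrays labelled mutant to that in control cells was 0.0182. Resampling these genes, which are not replicates, gave a 95% range of -0.0102 to 0.0719. The slope over all 121 such bright genes was 0.607. Ratio and slope rest in part on the arrays labelled mutant without H2O2. At bright probes the variance between those 2 replicates was 136 times that of duplicate spots. Choosing the 21 by their response in control cells, the ratio's denominator, favours a ratio near 0. These values point in different directions, so the bright genes do not settle it.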

How the results depend on the processing

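Counts of genes are given in the order mutant against control without H2O2, the same with H2O2, H2O2 in control cells, H2O2 on the arrays labelled mutant, and interaction, with 4791, 4836, 1637, 2 and 700 as reported. The cause of a change was not tested unless stated. Requiring genes well above background on all 8 arrays, or at least 100 units there (added after seeing the data), left fewer genes to test and gave 948, 970, 409, 0, 221 (129 at an unadjusted p under 0.05 for the limma count of 0) and 116, 119, 4, 0, 1 (43 for the 0). For the last 3 comparisons quantile normalization gave 110, 91, 11, normexp 4235, 0, 3382 (153 unadjusted for the 0), normexp with quantile 59, 147, 56, the spike-in scale 986, 1, 463, and the control arrays without H2O2 averaged 124, 0, 0 (475 and 1141 unadjusted for the 0s). The compared arrays alone gave 3473 for H2O2 in control cells, 1558 of them shared, and 0 (352 unadjusted) on the arrays labelled mutant. A log2 change of at least 1 left 894 for H2O2 in control cells. On the arrays labelled mutant a trend with robust variance gave 5, the percentile over well-measured genes 1 (interaction 350), the unpaired test named in the table headers 1, and an adjusted p under 0.1 26 (interaction 1317). With the replicate number as a block the counts were 4729, 4822, 1420, 0, 496 (724 unadjusted for the 0) and the called lists 21, 18, 25, 1 and 16. The labels do not say whether the numbers mark a shared batch. Replicate differences correlated between groups at -0.0725 to 0.211, the highest between the control groups without and with H2O2. The block moved no count by over 1.5 times other than that to 0. Leaving out 1 array gave 4193 to 4850, 4472 to 5077, 85 to 2263, 0 to 328 and 0 to 1240 genes, the lone array of a group being assumed to vary like the others. For H2O2 in control cells 85 and 291 were called without replicate 1 or 2 of the control arrays without H2O2 and 532 without replicate 2 of those with H2O2. On the arrays labelled mutant 184 and 328 were called without replicate 1 or 2 of the group without H2O2, and 0 without each other array (475 to 899 unadjusted). The interaction gave 0 without either control array without H2O2 (1097 and 1185 unadjusted), 121 without replicate 2 of the control arrays with H2O2, 1240 without replicate 2 of the mutant group without H2O2, and 365 and 327 without replicate 1 or 2 of the mutant group with H2O2. Of lists, camera with an estimated correlation called 0, 0, 2, 0 and 0 (10, 11, 8, 0 and 5 unadjusted), fry 40, 41, 32, 0 and 23 (2 unadjusted for the 0), and quantile normalization 11 with H2O2; leaving out 1 array gave 21 to 22, 18 to 20, 22 to 25, 1 to 1 and 15 to 21. The correlation of the H2O2 responses was 0.0406 after quantile normalization, 0.0991 after normexp, 0.188 over genes well above background on all 8 arrays and 0.0514 to 0.0699 without 1 array, and that of the strain differences 0.934 after quantile normalization and 0.928 to 0.958 without 1 array. Of single genes, log2 changes turned sign on the spike-in scale without H2O2 for ENA5 -0.045, BI4 -0.23, BI3 -0.40, GMC2 -0.44, ECM12 -0.89, ARN2 -0.90, AYT1 -0.97, COS8 -1.05, MF(ALPHA)1 -1.10, RPL40A -1.65, RPL7B -7.76, RPS0B -8.54, GPM1 -3.49, ADH4 -7.63 and ENO1 -3.27, and with H2O2 for GLN1 -0.28, PET9 -0.36, ATP2 -0.45, BI4 -0.45, RDS1 -0.58, MF(ALPHA)1 -0.58, COS8 -0.60, BI3 -0.71, RPL40A -1.85, RPL29 -3.92, RPS23B -3.22, GPM1 -3.21, PDC6 -5.95, ENO1 -2.43 and ADH4 -7.51, as that scale shifts all genes down. These are fitted values, which are not folds for probes with only a bound or, as BI3 and ADH4 with H2O2, with none. RPS0B was at -0.31 after normexp, and GPM1 at -0.24 without and -0.13 with H2O2 in the authors' deposited normalized values. SUA7, not called for H2O2 in control cells, was at -0.53 on the spike-in scale, -0.010 after quantile normalization, -0.012 after normexp, -0.024 after both, and -0.25 to 0.27 without 1 array (below 0 without replicate 2 of either control group), and its interaction was -0.13 to 0.39 without 1 array (below 0 without replicate 1 of either control group). The other named values kept their direction: 1150 of those for H2O2 in control cells stayed on their side of the threshold and 207 fell short, with 694 and 3 for the strains without H2O2, 709 and 5 with H2O2, 157 and 74 for the interaction, and 230 and 11 on the arrays labelled mutant, where 47 newly passed. The interaction from the compared arrays alone and the authors' values for the H2O2 comparisons and the interaction were not run, as the former needs all groups and each table holds 1 medium. Signal over background limits every comparison that involves the arrays labelled mutant.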

Other observations

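All tests of the explanations weighed here were chosen after the result was seen, except that on Yap1 targets, and the bright genes named below were picked after their values were seen.

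Camera called further lists down with H2O2 in control cells, none of which held with an estimated correlation. In the citric acid cycle 11 of 18 genes fell, 16 adjusted over the list alone (median -0.83, -1.37 to -0.50 over scalings; camera adjusted p = 1.21e-06; adjusted p = 0.0627 with an estimated correlation). Of genes raised in stationary phase, 17 of 20 list members fell, 17 adjusted over the list alone (median -1.44, -1.98 to -0.63 over scalings; camera adjusted p = 2.56e-08; adjusted p = 0.261 with an estimated correlation). In autophagy 16 of 26 genes fell, 16 adjusted over the list alone (median -0.92, -1.47 to -0.37 over scalings; camera adjusted p = 2.61e-05; adjusted p = 0.261 with an estimated correlation), and in peroxisomal fatty acid oxidation 12 of 22 genes fell, 12 adjusted over the list alone (median -0.73, -1.28 to -0.28 over scalings; camera adjusted p = 4.4e-05; adjusted p = 0.261 with an estimated correlation). Among transport, flavour and alcohol genes 13 of 24 genes fell, 14 adjusted over the list alone (median -0.72, -1.26 to -0.34 over scalings; camera adjusted p = 3.23e-05; adjusted p = 0.261 with an estimated correlation). Of genes used without oxygen, 13 of 24 list members fell and 1 rose, 13 and 2 adjusted over the list alone (median -0.91, -1.45 to -0.36 over scalings; camera adjusted p = 0.0129; adjusted p = 0.412 with an estimated correlation). For poor nitrogen sources 9 of 29 genes fell and 1 rose, 12 and 1 adjusted over the list alone (median -0.54, -1.08 to -0.19 over scalings; camera adjusted p = 0.000225; adjusted p = 0.261 with an estimated correlation).

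Other lists gave the following counts. In the pentose phosphate pathway 7 of 19 genes fell, 7 adjusted over the list alone (median -0.49, -1.03 to -0.34 over scalings; camera adjusted p = 0.0120; adjusted p = 0.261 with an estimated correlation), and in glycerol and osmotic response 6 of 20 genes fell and 1 rose, 6 and 1 adjusted over the list alone (median -0.31, -0.85 to -0.15 over scalings; camera adjusted p = 0.0328; adjusted p = 0.426 with an estimated correlation). In meiosis and sporulation 5 of 25 genes fell, 4 adjusted over the list alone (median -0.31, -0.85 to -0.0032 over scalings; camera adjusted p = 0.0372; adjusted p = 0.426 with an estimated correlation), and in the cell wall 8 of 37 genes fell and 1 rose, 8 and 1 adjusted over the list alone (median -0.20, -0.74 to -0.17 over scalings; camera adjusted p = 0.0383; adjusted p = 0.271 with an estimated correlation). For mitochondrial ribosomal proteins 2 of 53 genes fell, 0 adjusted over the list alone (median -0.20, -0.74 to -0.077 over scalings; camera adjusted p = 0.0418; adjusted p = 0.615 with an estimated correlation). For RNA polymerase II, Mediator and SAGA, where the median turns to -0.21 on the spike-in scale, 10 of 51 genes rose and 1 fell, 5 and 0 adjusted over the list alone (median 0.33, -0.21 to 0.37 over scalings; camera adjusted p = 0.00738; adjusted p = 0.188 with an estimated correlation). For histones and replication, where it turns to -0.16, 3 of 30 genes rose, 3 adjusted over the list alone (median 0.38, -0.16 to 0.42 over scalings; camera adjusted p = 0.0105; adjusted p = 0.426 with an estimated correlation). Glycolysis and fermentation genes were not called (4 of 23 fell, median 0.11, mean -0.19, camera adjusted p = 0.945). Lists for other cell states gave camera adjusted p = 0.398 for a-mating genes and 0.831 for alpha-mating genes.

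Some of these lists differed between strains on the 75th percentile scale. Meiosis genes were higher on the arrays labelled mutant at 25 of 25 without and 24 of 25 with H2O2, the same adjusted over the list alone (medians 4.36 and 5.25; adjusted p = 0.206 and 0.192 with an estimated correlation), but on the spike-in scale the medians were -6.46 and -4.89. Alpha-mating genes were higher at 7 of 8 in both media, the same adjusted over the list alone (medians 2.83 and 2.86; adjusted p = 0.287 and 0.325 with an estimated correlation), and on the spike-in scale -7.99 and -7.28. Proteasome genes were lower at 33 and 29 of 36, the same adjusted over the list alone (medians -1.84 and -1.95; adjusted p = 0.0594 and 0.0825 with an estimated correlation), and ergosterol genes at 20 and 23 of 28, the same adjusted over the list alone (medians -2.29 and -2.57; adjusted p = 0.102 and 0.112 with an estimated correlation). Among the 122 genes with at least 100 units on all 4 arrays labelled mutant were the histone genes HTB2 (1525 to 3368 units) and HHF2 (14674 to 25437 units), the translation elongation factor genes TEF1 (54607 to 343353 units) and EFT2 (25779 to 191237 units), and the glycolytic gene TDH3 (5156 to 7655 units). These named genes have close copies in the genome and are uncertain as to copy. The share of such genes among the 122 was not analysed here.

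The arrays labelled mutant were dim at most probes. A failed labelling or scan is argued against by the spike-in probes, whose mean was 1.23 times that of the control arrays. An equal loss of yeast RNA is argued against by a 5th to 95th percentile span of 10.99 in the log2 ratio among the tenth of genes brightest on the control arrays. A transcript loss in growing cells through the changed TFIIB was weighed with the general transcription factor list, mostly genes a growing cell needs. That explanation predicted that most members keep over 1% of the control signal, but 100% lay under it on all 4 arrays. This covers the genes of that list alone. In lists matched on control signal a median of 97.2% of genes lay there too (4265 of 10000 reached 100%), so the list is not set apart by its dimness. The test therefore decides nothing, and this explanation stays open. RNA mainly from another organism predicted an excess of ribosomal protein genes that kept 1% of the control signal, and this was not met: 9.56% did, against a 95th percentile of 9.56% and a median of 7.35% of lists matched on control signal (8.51% of 10000 lists were as high), but the matched lists come from the same brightest genes, so the test decides little. Degraded RNA, and a wrong or outside sample, were not tested and may also account for the pattern.

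In control cells with H2O2, camera called the ribosome biogenesis list up and the gluconeogenesis and glyoxylate list down, and neither held with an estimated correlation (adjusted p = 0.0627 and 0.261). For the former, a brightness-dependent difference between arrays is argued against by its median of 1.00, outside the range of -0.079 to 0.19 that held 95% of 10000 lists matched on signal. A running Yap1 response to peroxide predicted a rise of the Yap1 target list, in the only test set beforehand. This was not met, as the median was -0.32 (95% -0.59 to -0.091). That median is over 22 genes, which are not replicates. The environmental stress response list fell as well (median -2.34). The test therefore cannot tell an absent Yap1 response from one hidden by a wider difference between the cultures. Cultures collected at different points of glucose use stay open and untested, because glucose and growth time were not analysed here.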
